A study of Mus musculus with 24 samples.

How the data were processed

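MicroRNA (miRNA) levels were measured in RNA from the inner lining (intima) of carotid arteries of male C57Bl6 mice aged 6 to 8 weeks. Per the labels, all but 1 of the caudal branches of the left carotid artery had been tied (partial ligation), which leaves low and oscillating flow in that vessel, as checked by ultrasound in each mouse. The right carotid artery of the operated mice served as the control. The intima was flushed out with a phenol-based lysis reagent, RNA was purified on a column kit, labelled with Cy3 and hybridised to an Illumina bead array of miRNA probes, per the labels' protocols. The 24 arrays fall into 4 groups of 6: left and right carotid at 12 h and left and right carotid at 48 h after surgery. The labels number the samples of each group but do not say whether the numbered samples came from separate animals, from pools or from both arteries of one animal, so every p-value measures the spread between these samples, which may be partly technical.

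The deposited non-normalized tables, 1 per time point, give for each of 655 probes on each array an average signal intensity and a detection p-value. Both were exported from GenomeStudio 2010.2, per the submitters' processing notes. No intensity was below 0, and whether background had been subtracted is not given in the sources used here. The authors' processed intensity values were also deposited. Set against the tables, they matched quantile normalization of the signals within each time point with no background subtraction, on a linear scale (median difference 0.194% at 12 h and 0.476% at 48 h). Their column medians lay between 1069 and 1079 at 12 h and between 559 and 568 at 48 h, and they were left blank for nearly all probes detected on no array of the time point. The array columns carry the artery and the number but not the time. Each table was tied to its time point through the processed values, whose rank order matched the column of the same artery and number (rank correlation at least 0.99998) and no column of the other time (at most 0.759). The files name no slide, scan date or saturation, so these were not examined. They give a chromosome and start for most miRNAs without naming the genome build. Each miRNA's gene was looked up by name in RefSeq's mouse annotation of assembly GRCm38.p6. Host genes were the other genes whose coordinates in that annotation enclosed it, on either strand. Of the 71 miRNAs named by the rule below, 56 had a single locus in the files, 44 matched a RefSeq gene and 30 lay inside another gene.

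Before groups were compared, arrays were compared with each other. At 12 h, arrays 1 and 4, 2 and 5, and 3 and 6 of each artery had rank correlations between 0.986 and 0.998, while no other pair exceeded 0.877. Arrays above 0.98 were therefore treated as repeat arrays of 1 sample and averaged, which leaves n = 3 per artery at 12 h, and samples 1 to 3 stand for these pairs. No such pairs occurred at 48 h, where n = 6 per artery. The fits had been laid out for 6 samples per group, and the fit with every array as a sample is kept as an alternative.

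Signals were background-corrected and quantile-normalized within each time point with neqc (limma 3.58.1 in R 4.3.3), which estimated the background from the detection p-values and added an offset of 16 before log2. A probe was tested if its detection p was under 0.05 on at least 3 arrays of at least 1 group compared. Left and right were compared at each time with limma's lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. The difference of the left-right change between times was a contrast over all samples. Each artery was also compared between times after all arrays were normalized together. Time point and deposited table coincide there, so those counts are descriptive. Where a probe was undetected on every array of a group, a fitted change is no bound. The bound printed as "at least N-fold" sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own signal, on normalized values.

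Before the data were examined, 27 lists were fixed from memory: markers of smooth muscle, striated muscle, endothelium, erythroid cells, leukocytes, fibroblasts, neurons, epithelium and liver; miRNAs published as raised by low or disturbed flow, as raised by laminar flow, as inflammatory, as hypoxic or as mapping to pre-ribosomal RNA; the let-7, miR-29, miR-30, miR-15/16, miR-26, miR-34 and miR-181 families; the miR-23/27/24, miR-17-92, Dlk1-Dio3 and Sfmbt2 clusters; and the sets remembered as raised and as lowered in the study's own publication, which were chosen on these samples. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives. The named miRNAs were fixed by a rule: at each time the 10 largest rises and falls past the threshold, filled to 5 per direction by smallest p; for the difference between times the 5 largest per direction past the threshold, filled in the same way; up to 4 members of each list by smallest p; and a fixed set that includes miR-712, miR-126-3p, miR-126-5p, miR-143, miR-145, miR-451, miR-223, miR-21, miR-92a and miR-155. In applying it, at most 2 members per list were added, at 48 h only, to limit length. That choice was made after values had been seen, and the count of samples standing apart from their group covers this smaller set. The other names are said to have been chosen after their values were seen.

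The scripts were tested on simulated data in which 60 miRNAs were changed in each of 20 runs. With quantile normalization, a log2 change of 1, 2 and 4 was found for 26.3%, 51.5% and 77.3% of changed miRNAs at 12 h (430 miRNAs), for 25.0%, 54.8% and 75.3% at 48 h (407 miRNAs), and for 9.75%, 30.0% and 58.0% in the difference between times (474 miRNAs). The share of calls that were false was 4.52% at 12 h and 3.08% at 48 h for the fit alone, but 14.8% and 13.5% when quantile normalization followed the simulated change, above the nominal 5%. The number of arrays, and the signal over background of dim probes, limit the precision. Alternatives covered background correction, normalization, the authors' values, the detection filter, the replicate number as a block, the trend, array weights and leaving out each sample. A slide block could not be run because the files name no slide. Alternatives added after the data had been seen were every array as a sample, the 2 or the 3 right arrays with the fewest detected probes left out, the detected number as a covariate, tests limited to probes detected on all arrays, list tests with each sample left out, and list tests adjusted without the 2 remembered sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.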

Results

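The arrays addressed which miRNAs of the carotid intima respond to disturbed flow. The partially ligated left carotid of the mouse was set against the right carotid, 12 h and 48 h after surgery. The groups hold no arteries of sham-operated or unoperated mice. Effects of flow, of the surgery itself and of the side of the body therefore cannot be told apart. The study's stated interest was the 48 h time point. Detected probes per array ranged from 335 to 431 of 655. At 12 h the left arrays detected 411 ± 14.8 probes and the right arrays 383 ± 14.6 (SD, n = 3 samples each; two-sided exact permutation p = 0.2, where 0.1 is the smallest possible). At 48 h the numbers were 378 ± 15.3 and 371 ± 33.3 (SD, n = 6 each; exact permutation p = 0.671). Right arrays 4, 1 and 2 at 48 h detected the fewest, 335, 336 and 356. Median raw signals ranged from 332 to 1030 at 12 h and from 119 to 500 at 48 h.

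At 12 h, the arrays paired within each artery differed by less than any other arrays did and were counted as 1 sample per pair. Paired arrays disagreed on the detection of a median of 15.5 probes, against 85.5 between different samples of a group. Of all 18 samples, 3 right ones had a higher mean rank correlation with the left samples of their time than with the other right samples: right sample 1 at 12 h (0.866 against 0.845), right sample 3 at 48 h (0.806 against 0.800) and right sample 5 at 48 h (0.811 against 0.789). Without these samples, taken one at a time, 2, 12 and 14 miRNAs passed the threshold, among them 1 of the 2 calls given for 12 h and 8 and 10 of the 12 given for 48 h. All 3 were kept under their labels. None of the 9 left samples lay nearer to the right ones, and a single wrong label was not tested.

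**Figure D1:**
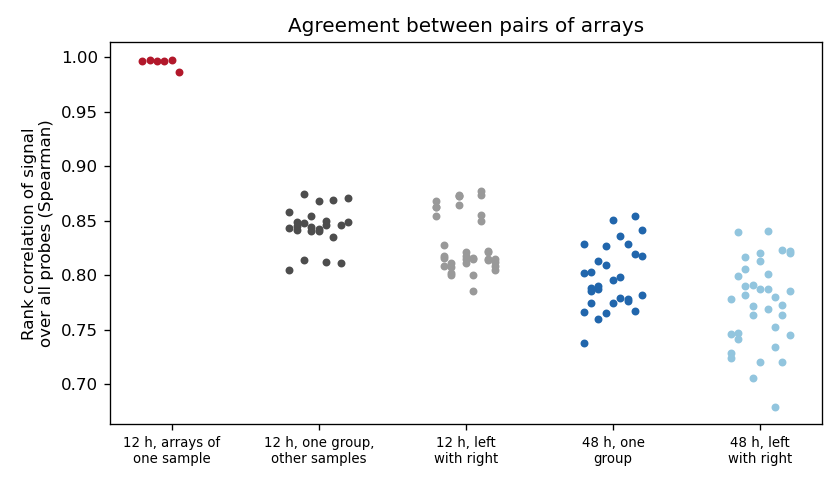
Spearman rank correlation of the signals of pairs of arrays (1 point per pair) at 12 h and 48 h, by whether both arrays come from 1 sample, from different samples of 1 group, or from left and right arteries. The 6 pairs of repeat arrays at 12 h lie between 0.986 and 0.998, above all other pairs, whose highest value at 12 h is 0.877.

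At 12 h after ligation, 2 miRNAs were higher in the left carotid and none were lower among 430 tested. The larger rise was in miR-291b-5p, a member of the miR-290 to miR-295 cluster known from embryonic stem cells. It was detected on 6 of 6 left arrays and 0 of 6 right arrays, at mean log2 signals of 11.16 ± 0.10 and 6.06 ± 0.09 (SD, n = 3 each), which is at least 10.6-fold higher on the left (fitted log2 change 5.09 ± 0.32 SE, limma adjusted p = 0.00208). miR-872*, the minor strand of a miRNA within the gene Ift74, was likewise detected on 6 left and 0 right arrays and was at least 7.32-fold higher (fitted log2 change 3.50 ± 0.44 SE, adjusted p = 0.0497). For both, all 3 left samples lay above all 3 right samples. The files place miR-291b-5p on chromosome 7 from position 3219494 (plus strand) and miR-872* on chromosome 4 from position 94331896 (plus strand), in an unnamed build. By limma, 41 miRNAs had an unadjusted p under 0.05, against 21.5 expected by chance. In 82 of 430 (19.1%) the left and right samples did not overlap, against 10% expected by chance for 3 against 3. The call of miR-872* was lost when any of the 6 samples was left out (adjusted p between 0.0571 and 0.146). miR-291b-5p stayed past the threshold in all 6. It was the only one to pass without left sample 1, left sample 3, right sample 2 or right sample 3, and without left sample 2 or right sample 1 the count was 2, with 1 other miRNA in place of miR-872*. A count of 72 (35 higher, 37 lower), chosen after the data were seen, resulted when every array was treated as a sample. With the replicate number as a block, 0 passed (limma, miR-291b-5p adjusted p = 0.0907), though the labels do not tie this number to an animal.

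At 12 h, 0 members of the flow and inflammation lists passed over all miRNAs (limma). Adjusted over the list alone, 2 of the low or disturbed flow list (miR-21 and miR-155) and 3 of the inflammatory list (these and miR-9) did, and 0 of the laminar flow list. So did 2 of the striated muscle list (miR-1 and miR-133a), miR-9 in the neural list and miR-23a in the miR-23/27/24 clusters. miR-155, an inflammatory miRNA, had a log2 change of -0.99 ± 0.27 SE (adjusted p = 0.297), miR-21 one of -0.14 ± 0.04 SE (adjusted p = 0.265) and miR-23a one of -0.24 ± 0.06 SE (adjusted p = 0.280). Values for the endothelial miR-126-3p and miR-126-5p were -0.05 ± 0.04 SE and 0.01 ± 0.01 SE. Leaving out 1 sample gave 0.00 to 0.01 for miR-126-5p. Quantile normalization gives probes of equal rank equal values, so its small SE is no measure of stability. For the smooth muscle miR-143 and miR-145 they were -0.03 ± 0.24 SE and -0.27 ± 0.12 SE, and for the myeloid miR-223 0.70 ± 0.23 SE (adjusted p = 0.373). miR-712 maps to pre-ribosomal RNA and is known as a flow-sensitive miRNA in mouse endothelium. It is also a member of the remembered raised set. It stood at 0.72 ± 1.76 SE (limma adjusted p = 0.902), detected on 6 left and 4 right arrays. Other values below the test's threshold were 0.62 for miR-1186, 0.84 for solexa-3253-144, 2.56 for miR-154, -0.33 for miR-574-5p and -0.26 for let-7d*, with adjusted p between 0.201 and 0.251. The remaining miRNAs of the fixed set stood at 0.20 for miR-451, -0.20 for miR-92a, -0.10 for miR-10a, -0.14 for miR-146a, -0.13 for miR-210, -0.02 for let-7d, 0.01 for miR-195, -0.08 for miR-30c, -0.30 for miR-29b, -0.04 for miR-26b and 0.07 for miR-770-5p. None of the 20 lists tested with camera passed (1 had an unadjusted p under 0.05), and fry gave 0 as well. The smallest camera value was that of the miR-23/27/24 clusters, whose 5 members all had values below 0 (adjusted p = 0.150). Without left sample 3 it was 0.0533, and 0.0480 when also adjusted without the 2 remembered sets (adjusted p = 0.773 with an estimated correlation). By fry's test for change in either direction, the striated muscle (adjusted p = 0.0306), leukocyte (0.0144) and inflammatory (0.0359) lists passed. The median log2 change of all miRNAs was -0.05 and became 0.11 when arrays were scaled to their 75th percentile, and under that scaling the let-7 family went from 8 of 9 members below 0 to 8 of 9 above 0.

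At 48 h, 12 of 407 miRNAs differed between the arteries, 8 higher and 4 lower on the left. Among the rises, miRNAs with few detected right arrays were miR-669e, a miRNA of the Sfmbt2 intron (log2 change 4.88 ± 1.11 SE, adjusted p = 0.0315, detected on 6 left and 1 right arrays), miR-330*, within Eml2 (4.70 ± 1.01 SE, adjusted p = 0.0277, 6 left and 2 right arrays), and miR-146b, a target of NF-kB that damps innate immune signalling (4.63 ± 0.97 SE, adjusted p = 0.0276, 5 left and 1 right arrays). With most right samples of these 3 at background, the fitted sizes depend on the background level and their order was not read. miR-615-5p, in the Hoxc5 gene, rose by 1.62 ± 0.35 SE on the log2 scale (adjusted p = 0.0277). Among bright miRNAs, miR-423-3p rose by 0.89 ± 0.16 SE, miR-99b by 0.36 ± 0.09 SE and miR-574-3p by 0.30 ± 0.05 SE (adjusted p = 0.0197, 0.0432 and 0.0162). The fourth bright riser, the sequencing-derived probe solexa-284-1594, whose target GGCTCGTTGGTCTAGGGGTATGATTC resembles the 5′ part of a proline tRNA, rose 1.89-fold (log2 change 0.92 ± 0.14 SE, adjusted p = 0.0121).

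The 4 falls were in miR-327 (log2 change -1.98 ± 0.40 SE, adjusted p = 0.0252), let-7d, of a family that restrains proliferation (-1.02 ± 0.20 SE, adjusted p = 0.0227), miR-26a (-0.43 ± 0.09 SE, adjusted p = 0.0240) and miR-23b, a miRNA of laminar flow in cultured endothelium (-0.22 ± 0.05 SE, adjusted p = 0.0315). All 6 left samples lay below the right mean for each of the 4. For 7 of the 8 rises all 6 left samples lay above the right mean, and for miR-146b 5 of 6 did. Left and right samples did not overlap for solexa-284-1594, miR-574-3p, miR-423-3p, miR-99b, miR-615-5p, miR-330*, miR-26a and miR-327, and did for let-7d, miR-146b, miR-23b and miR-669e. Over all tested miRNAs, 19 (4.67%) had groups that did not overlap, against 0.216% expected by chance, and 72 had an unadjusted p under 0.05, against 20.35 expected. The fifth fall by p, miR-743a, did not pass (adjusted p = 0.0892; adjusted p = 0.00997 without right sample 1). It was undetected on all left arrays and detected on 5 right ones, at least 2.80-fold lower on the left.

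**Figure D2:**
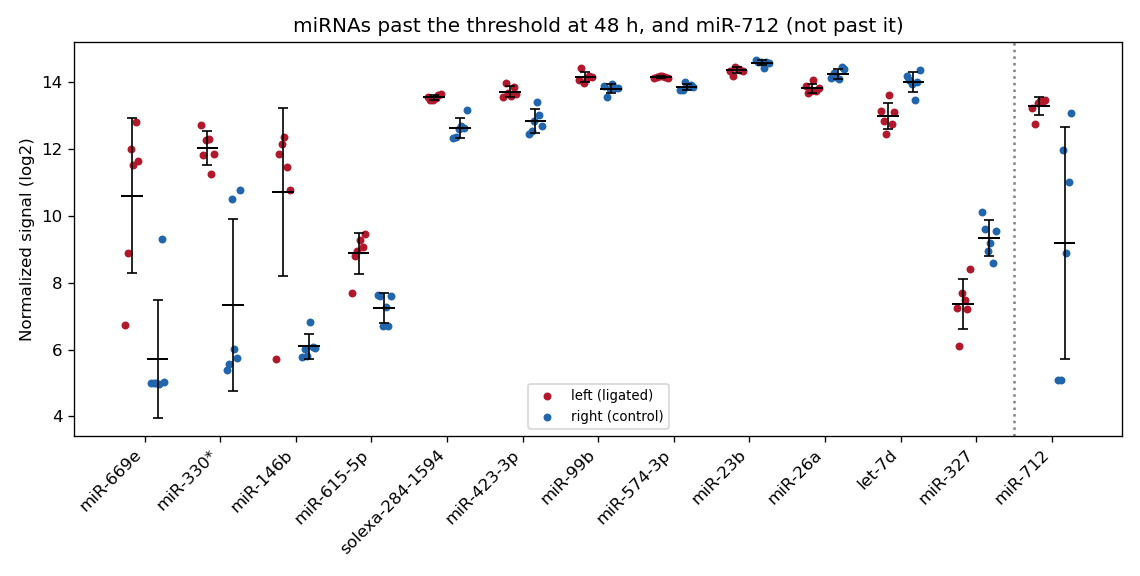
Normalized log2 signal of each sample at 48 h (6 left, red; 6 right, blue) for the 12 miRNAs past the threshold and, right of the dotted line, miR-712, which was not past it. Horizontal bars give the mean and error bars the SD; the groups are 0.22 apart for miR-23b and 4.88 apart for miR-669e, where 1 right sample lies with the left ones.

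The files place miR-669e on chromosome 2 from position 10389163, miR-330* on chromosome 7 from 19766873, miR-146b on chromosome 19 from 46417279 in the long noncoding gene Gm36493, miR-615-5p on chromosome 15 from 102845356, miR-423-3p on chromosome 11 from 76891611 in Nsrp1, miR-574-3p on chromosome 5 from 65361602 where Fam114a1 and Tlr6 overlap, and miR-99b on chromosome 17 from 17967157 in Spaca6. Of the miRNAs that fell, miR-327 starts at 45567177 on chromosome 14, let-7d at 48631469 on chromosome 13 and miR-23b at 63401836 on chromosome 13 in Aopep, all in the files' unnamed build. miR-26a has several loci, and no locus is given for miR-712 or solexa-284-1594.

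The calls at 48 h depended on single samples, and 0 passed with the replicate number as a block (limma), a number the labels do not tie to an animal. Without left sample 5 none of the 12 passed (limma; 66 of 407 had an unadjusted p under 0.05), without left sample 4 the count was 6, and without right sample 2 or right sample 6 it was 4. Leaving out 1 of the 12 samples ended the call of solexa-284-1594, miR-423-3p and miR-574-3p in 1 case (left sample 5), of let-7d and miR-26a in 3, of miR-327 in 4, of miR-330* and miR-146b in 5, of miR-615-5p in 6, of miR-669e and miR-23b in 9 and of miR-99b in 10. Scaling to the 75th percentile moved the median log2 change of all miRNAs from -0.00 to 0.32 and gave 8 higher and 1 lower, in place of 8 and 4. It ended the calls of miR-99b (0.42), miR-574-3p (0.38), miR-327 (-1.42) and miR-26a (-0.29), with adjusted p between 0.0600 and 0.127, and of miR-23b, at -0.08 (adjusted p = 0.708). Without the 2 right arrays with the fewest detected probes, an alternative chosen after the data were seen, 13 passed (6 higher, 7 lower), 7 of them among the 12. Without the 3 with the fewest, 6 passed, 4 of them among the 12.

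Of the sets remembered from the study's publication, the 4 measured members of the raised one all had values above 0. miR-330* passed. miR-712 was higher than the right mean in 6 of 6 left samples, with a log2 change of 4.11 ± 1.32 SE (adjusted p = 0.117), and was detected on 6 left and 4 right arrays, so that the right samples spread widely (mean 9.19, SD 3.46, n = 6, against 13.29, SD 0.27, on the left). miR-223 stood at 1.95 ± 0.60 SE (adjusted p = 0.107) and miR-770-5p at 2.01 ± 1.05 SE (adjusted p = 0.307; 0.90 without right sample 1), and miR-699n was not among the probe names. The raised set passed camera (median 3.06, adjusted p = 0.00496; adjusted p = 0.147 with an estimated correlation), with 1 member past the threshold over all miRNAs and 3 when adjusted over the list alone. In the lowered set, 5 of 5 values were below 0: let-7d passed, and miR-195 stood at -2.43 ± 0.73 SE (adjusted p = 0.104; -3.02 and adjusted p = 0.0219 without left sample 6), miR-29b at -2.02, miR-30c at -1.91 and miR-26b at -1.77 (adjusted p between 0.272 and 0.424). This set also passed camera (median -1.91, adjusted p = 0.00496; adjusted p = 0.437 with an estimated correlation), with 1 member past the threshold over all and 2 adjusted over the list alone. Left sample 3 read 68 for miR-29b, 37 for miR-30c and 190 for miR-26b in raw signal, the lowest of the 6 left samples for each. Without it the values were -0.96 for miR-29b (adjusted p = 0.290), -0.55 for miR-30c (adjusted p = 0.0449) and -0.90 for miR-26b (adjusted p = 0.122). The set's median without it was -0.92 (camera adjusted p = 0.000639; adjusted p = 0.105 with an estimated correlation). Both sets were chosen on these samples and are not independent evidence of their direction. Their members also stand in other lists, among them miR-712 and miR-30c in the flow lists, miR-223 in the leukocyte list and let-7d in the let-7 family. Those lists are to that extent not independent of these samples either.

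miRNAs published as raised by laminar flow had lower values in the left carotid as a list: 14 of 15 tested members had values below 0, with a median of -0.32 (camera adjusted p = 0.0145; adjusted p = 0.437 with an estimated correlation and 0.158 with fry). The adjustment runs over lists that include the 2 remembered sets chosen on these samples. Without these sets the adjusted p was 0.0391, though the list still holds miR-30c of the lowered set. Adjusted in that way, the list did not pass in 6 of 12 fits with 1 sample left out. They were the fits without left sample 1, 3 or 6 (adjusted p = 0.0612, 0.0910 and 0.0699) or right sample 3, 5 or 6 (0.150, 0.218 and 0.136). Adjusted over all lists, it did not pass without right sample 3, 5 or 6 (adjusted p = 0.0555, 0.0808 and 0.0504). Its median was -0.57 without left sample 2, -0.68 without left sample 5, -0.54 without right sample 1 and -0.63 without right sample 2, fits chosen after the data were seen. Of its members miR-23b fell, 1 member past the threshold over all and 2 adjusted over the list alone. miR-145 stood at -0.21 ± 0.06 SE (adjusted p = 0.0992; 0.0491 without right sample 2), miR-143 at -0.31 ± 0.14 SE (adjusted p = 0.262), miR-126-5p at -0.63 (adjusted p = 0.533; -1.14 and adjusted p = 0.0302 without right sample 4) and miR-10a at -1.20 (adjusted p = 0.424; -0.55 without right sample 6). The list holds the smooth muscle markers miR-143 and miR-145, and miR-30c and miR-30d, for which left sample 3 stood apart as low. Without left sample 3, 11 of the 15 were below 0 and the list's median was -0.24 (adjusted p = 0.0442 over all lists; adjusted p = 0.219 with an estimated correlation). Under 75th percentile scaling 12 of the 15 were below 0 (median -0.13, adjusted p = 0.0248, 0.0447 without the remembered sets, and 0.365 over all lists with an estimated correlation). Of the 7 tested miRNAs published as raised by low or disturbed flow, 5 had values above 0 (median 0.03, mean 1.07, camera adjusted p = 0.256). Past the threshold were 0 over all and 3 adjusted over the list alone. Among those above 0 was miR-712, also a member of the raised set chosen on these samples, so the list is not independent of them. The epithelial miR-200c stood at 4.37 ± 1.23 SE (limma adjusted p = 0.0898, 0.0277 without right sample 3 and 0.0283 without right sample 5). miR-21 stood at 0.02 (adjusted p = 0.896) and miR-92a at 0.03 (adjusted p = 0.866). The inflammatory list went both ways, 4 above and 5 below 0 (median -0.24, mean 0.45, test upward, adjusted p = 0.773), with miR-146b past the threshold over all and 2 adjusted over the list alone, and fry's test for change in either direction passed (adjusted p = 0.0361). miR-146a, also in that list, stood at -0.32 (adjusted p = 0.896), and miR-155 and miR-205 were below the detection filter at 48 h. The hypoxia miRNA miR-210 stood at 0.66 ± 0.20 SE (adjusted p = 0.107). It is the 1 member of its list, so that adjusted over the list alone its p is the unadjusted 0.00686. The pre-ribosomal list of 2 tested had miR-712* at -0.30 (-0.46 to -0.15 leaving out 1 sample; median 1.90 with miR-712; 0.28 for miR-712* under 75th percentile scaling; 1 adjusted over the list alone).

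Markers of other cell types gave no list past the threshold at 48 h. The 3 leukocyte miRNAs tested had values above 0 (median 0.51, adjusted p = 0.326; 1 adjusted over the list alone, miR-223), with miR-150 at 0.51. Both smooth muscle miRNAs, miR-143 and miR-145, were below 0 (median -0.26; 0 past the threshold over all, 2 adjusted over the list alone). The 5 endothelial miRNAs had a median of -0.63 (adjusted p = 0.773), with miR-126-3p at 1.86 ± 0.87 SE (adjusted p = 0.272) and miR-221 at -1.79 ± 0.65 SE (adjusted p = 0.151). Striated muscle had 3 above and 2 below 0 (median 0.12, mean -0.56, test downward, adjusted p = 0.773). In that list miR-1, specific to muscle, stood at -4.12 ± 1.53 SE (adjusted p = 0.158), detected on 1 left and 4 right arrays, and miR-499 at 1.24 (0.40 to 2.22 leaving out 1 sample). The erythroid pair had a median of -0.80, with miR-451 at -1.63 (adjusted p = 0.407; -1.04 without left sample 5) and miR-486 at 0.03. Fibroblast markers, 2 above and 2 below 0, had a median of 0.09 and a mean of 0.38, opposite to the test's direction (adjusted p = 0.897), with miR-199b* at 1.71 (0.92 to 2.83 leaving out 1 sample) and miR-199a-3p/miR-199b at -0.37. The 3 neural miRNAs had a median of -0.23 and a mean of 0.82 (test upward, adjusted p = 0.706; 0.34 in the median under 75th percentile scaling), with miR-128 at 2.97 ± 0.82 SE (adjusted p = 0.0892; 0.0233 without left sample 4 and 0.0443 without left sample 6; 1 adjusted over the list alone) and miR-219 at -0.26 (-0.43 to -0.12 leaving out 1 sample). The 3 epithelial ones had a median of 0.37 (adjusted p = 0.706; miR-200c the 1 adjusted over the list alone), with miR-200b at -0.49. The liver miRNA miR-122 was not tested, being below the detection filter.

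Among families and clusters at 48 h, the let-7 family had 7 of 9 members below 0 (median -0.77, adjusted p = 0.0559, and adjusted p = 0.437 with an estimated correlation). The list passed under 75th percentile scaling (adjusted p = 0.00933, and 0.243 with an estimated correlation) and without left sample 1, 2 or 4 or right sample 4 (adjusted p = 0.0377, 0.0380, 0.0156 and 0.00256, and at least 0.142 with an estimated correlation). Adjusted without the 2 remembered sets, chosen on these samples, the family, which holds let-7d of the lowered set, had camera adjusted p = 0.101. It then passed under 75th percentile scaling (0.0168) and without left sample 4 (0.0281) or right sample 4 (0.00230), and did not without left sample 1 (0.0679) or 2 (0.0685). In it let-7d fell, the 1 member past the threshold over all and over the list alone, and let-7b stood at -0.29 (adjusted p = 0.135; -0.19 and adjusted p = 0.0426 without left sample 2). All 3 miR-29 members (median -1.38, adjusted p = 0.256; miR-29c at -1.38), all 5 miR-30 members (median -1.03, adjusted p = 0.294; miR-30d at -1.82; 4 of 5 below 0 under 75th percentile scaling) and 3 of 4 miR-15/16 members (median -0.88, adjusted p = 0.294; miR-497 at -1.71, and -0.97 without left sample 6 and -2.78 without right sample 2; 1 adjusted over the list alone) had values below 0. Left sample 3 stood low in several of these, at raw signals of 53 for miR-30d, 30 for miR-29a and 35 for let-7c. Without it, medians were -0.43 for let-7, -0.96 for miR-29 (2 of 3 below 0) and -0.55 for miR-30 (4 of 5 below 0), and miR-30d stood at -0.75. Both miR-26 members were below 0 as well (median -1.10, and -0.66 without left sample 3), of which miR-26a fell, over all and over the list alone. In the miR-23/27/24 clusters 4 of 5 were below 0 (median -0.16, adjusted p = 0.256, and 0.07 in the median under 75th percentile scaling), with miR-23b past the threshold over all and over the list alone and miR-23a at -2.46. The miR-17-92 cluster and its paralogs, known to promote proliferation, had 9 of 11 above 0 (median 0.35, adjusted p = 0.256), with miR-93 at 0.95 ± 0.28 SE (adjusted p = 0.104) and miR-18a at 0.56. The 3 tested miR-34 members had a median of 0.03 (adjusted p = 0.903), with miR-34b-3p at 1.37 (0.67 without left sample 5) and miR-34a at -1.21. The 2 tested miR-181 members had a median of -0.07 (0.10 under 75th percentile scaling), with miR-181a at 0.29 (adjusted p = 0.137; 1 adjusted over the list alone) and miR-181b at -0.42. The imprinted Dlk1-Dio3 cluster, 13 of 33 above 0, had a median of -0.04 (-0.03 with miR-300, undetected on the left, at its bound; 0.24 under 75th percentile scaling; adjusted p = 0.706), with miR-494 at -1.10 (adjusted p = 0.135). The Sfmbt2 cluster list, which does not include miR-669e, had 6 of 19 above 0 (median -0.18, also with miR-297c, undetected on the left, at its bound; 0.01 under 75th percentile scaling; adjusted p = 0.596), with miR-669a at -3.40 (adjusted p = 0.212).

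Between the times, the left-right change differed for 1 of 474 miRNAs. miR-291b-5p, detected on all left arrays at 12 h, was detected on 0 right arrays at 12 h and on 0 arrays of either artery at 48 h. It was at least 10.6-fold higher on the left at 12 h, and no fold can be given at 48 h. The fitted log2 difference, 48 h minus 12 h, was -4.95 ± 0.27 SE (adjusted p = 2.47e-09). It rests on signals at background in 3 of the 4 groups, so its size and error are not those of a measured change. The miRNAs next by p did not pass: miR-615-5p at 2.30 and miR-129-3p at -4.37 (adjusted p = 0.0899 for both), miR-742* at 3.99 and miR-190 at -1.89 (0.153 for both), let-7d at -0.998 (0.176), miR-742 at 0.95 (0.283) and miR-423-3p at 0.83 (0.289), with miR-324-3p at 1.36 and miR-551b at -1.48. For miR-712 the difference was 3.39 ± 2.35 SE (limma adjusted p = 0.658), for miR-330* 4.99 ± 1.71 SE (0.294) and for miR-195 -2.44 ± 1.07 SE (0.431), so that a change at 48 h alone was not shown for them. A probe entered this contrast if it passed the detection filter at either time. miR-742 was detected on 0 arrays at 48 h, and miR-330* was below the filter at 12 h. Their differences thus rest partly on signals at or near background. Time point and deposited table coincide in this contrast too. An unadjusted p under 0.05 was found for 49 miRNAs, against 23.7 expected. Leaving out left 12 h sample 1, 2 or 3 gave counts of 4, 9 and 4, and leaving out right 12 h sample 1 or left 48 h sample 1 gave 2, with miR-291b-5p among them each time. Of the miRNAs named here, miR-615-5p, miR-324-3p and miR-551b passed without left 12 h sample 2 (adjusted p = 0.0488, 0.0283 and 0.00293), miR-742* without left 12 h sample 3 (0.00191), miR-129-3p without right 12 h sample 1 (2.78e-09) and miR-615-5p without left 48 h sample 1 (0.0112). None of 21 lists passed for the difference (camera, 4 with an unadjusted p under 0.05; fry 0), and the remembered lowered set came closest (adjusted p = 0.0609; adjusted p = 0.746 with an estimated correlation). It passed under 75th percentile scaling (adjusted p = 0.0263) and in 8 of 18 fits with 1 sample left out. They were the fits without left 48 h sample 1, 3, 4, 5 or 6 (adjusted p = 0.0322, 0.00512, 0.0289, 0.0440 and 0.00805) or right 48 h sample 3, 4 or 6 (0.0376, 0.0265 and 0.0452). With an estimated correlation the adjusted p over the 18 fits was at least 0.196. The raised set passed without right 48 h sample 3 or 6 (adjusted p = 0.0376 and 0.0452; 0.208 and 0.526 with an estimated correlation) and the let-7 family without right 48 h sample 4 (adjusted p = 0.0203, and 0.0184 without the remembered sets; adjusted p = 0.579 with an estimated correlation).

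Across the 363 miRNAs tested at both times, the left-right changes at 12 h and 48 h had a Pearson correlation of 0.209 and a Spearman correlation of 0.151. These are correlations across miRNAs, which are not independent replicates. The sign was the same for 57.6%, and 0 calls were shared, against 0.0193 expected for independent lists of rises. Only 1 call at 12 h was among these miRNAs, so the lack of shared calls says little about agreement between the times.

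**Figure D3:**
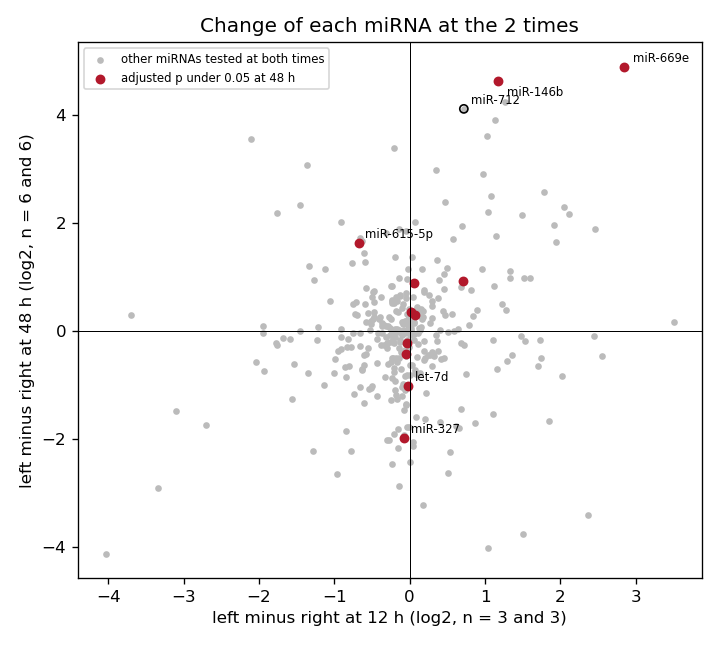
Left minus right log2 change at 12 h (x axis) against 48 h (y axis) for the 363 miRNAs tested at both times, 1 point per miRNA, with the 48 h calls in red and miR-712 outlined in black. The Pearson correlation is 0.209, and miR-291b-5p and miR-330*, each tested at one time only, are not shown.

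Between 12 h and 48 h, miRNAs differed within each artery, in a comparison where time and deposited table coincide. In the right carotid 60 of 474 had higher and 47 lower log2 signals at 48 h, and in the left carotid 99 and 92 (adjusted p under the threshold, limma). The split turned on the scaling: 26 and 111 on the right and 40 and 137 on the left with 75th percentile scaling, 31 and 66 and 42 and 98 with the authors' values. The median log2 change of all miRNAs went from 0.13 to -0.68 and -0.41 on the right and from 0.22 to -0.57 and -0.31 on the left under these scalings. In detection, which does not rest on the scaling, miR-295, miR-683, miR-742 and miR-878-3p were detected on all 12 arrays at 12 h and on 0 at 48 h, and miR-294, miR-302c, miR-196a* and miR-197 on 0 at 12 h and all 12 at 48 h, names chosen after their values were seen. Rank correlations between arrays of different times lay between 0.586 and 0.785.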

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

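The patterns weighed here were noticed in the data before their tests were chosen, and the fits with the detected number as a covariate and without the 3 right arrays with the fewest detected probes were added after the results at 48 h had been seen. What each of these tests would have to show was set down before its own result was computed, and for miR-291a-5p the outcome set down was later set aside.

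In 27 of 116 groups of 6 samples at 48 h (23.3%), the highest or lowest sample lay so far from the nearest other that the gap's share of the group's range was above Dixon's 95% critical value. For independent, normally distributed values chance gives about 1 in 20 such groups, 5.8 here. Some of these groups hold signals at background, such as the left samples for miR-743a and miR-297c, undetected on all left arrays. The count is thus not read as an excess of odd samples. The odd sample was low in 18 and high in 9, most often right sample 4 (6 times), left sample 3 (5) and left sample 2 (4). Among miRNAs past the threshold the gap's share of the range was 0.991 for miR-669e in right sample 5 (high), 0.761 for miR-146b in left sample 1 (low) and 0.734 in right sample 4 (high), 0.626 for miR-615-5p in left sample 1 (low) and 0.642 for miR-23b in right sample 4 (low). Left sample 3 stood low for miR-30c (0.918), miR-29b (0.647), miR-26b (0.761) and miR-30d (0.676) and high for miR-200b (0.648). Left sample 2 stood low for miR-712 (0.667) and let-7b (0.777) and high for miR-29c (0.726) and miR-297c (0.879), and left sample 6 stood high for miR-743a (0.680) and miR-1 (0.997). Right sample 1 stood high for miR-743a (0.717) and low for miR-770-5p (0.861). Right sample 2 stood low for miR-145 (0.800) and miR-497 (0.725) and high for miR-30c (0.722), and right sample 3 stood low for miR-195 (0.634) and miR-29b (0.649). Right sample 4 stood low for miR-126-5p (0.754), miR-150 (0.695), let-7b (0.675) and miR-23a (0.812).

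Many miRNAs at 48 h were detected on some samples of a group and not on others, 278 probes in all. Real differences between samples in transcription of a locus should make miRNAs within 10 kb of each other deviate together. Over 65 such pairs the median correlation of their deviations was -0.0403 (bootstrap SE 0.0688), beside 0.00392 for miRNAs on different chromosomes. Every miRNA in these pairs was undetected on some arrays, where its signal is background, and the SE takes overlapping pairs as independent. No joint deviation was seen, but whether this test would have found one was not checked, so the cause stays open. A few arrays of low yield cannot be told apart from a spread over all arrays. Of 83 gaps in miRNAs detected on all but 1 array of a group, right arrays 1 and 4 held 34.9%, between the shares set beforehand for either reading. No biological explanation other than local transcription was tested.

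The 12 miRNAs that differed between the arteries at 48 h may owe part of their calls to uneven arrays. With the number of detected probes as a covariate, 12 of 12 kept their direction and at least 50% of their log2 change, and 11 stayed past the threshold, with miR-99b going from 0.36 ± 0.09 SE to 0.35 ± 0.09 SE. The covariate moved the 12 by at most 5.72% and the 395 others by a median of 0.0956 and up to 0.62 (log2). Since the number averaged 378 and 371 in the arteries, the covariate could move a left-right change only little. Keeping at least 50% was thus near certain, and the fit cannot weigh uneven arrays beyond a difference in that average. Without the 3 right arrays with the fewest detected probes, 12 of 12 again kept that much, but only 4 stayed past the threshold: miR-330* went from 4.70 ± 1.01 SE to 3.02 ± 1.03 SE, a smaller change, and miR-146b from 4.63 ± 0.97 SE to 4.75 ± 1.37 SE, a larger error with fewer samples. Of the other calls lost, let-7d (-1.02 to -1.12), miR-615-5p (1.62 to 1.87) and miR-23b (-0.222 to -0.237) had larger changes. Those of miR-327 (-1.98 to -1.67), miR-669e (4.88 to 4.16) and miR-99b (0.357 to 0.346) were smaller. The changes were thus also present against the other right arrays, but the 12 had been chosen on a fit that holds those arrays too. Where left and right samples did not overlap, leaving out right arrays could not turn the direction. Keeping it therefore says little. How much the 3 arrays add to the calls, as for miR-330* whose change became smaller, stays open. At 48 h the real split gave 12 and the highest of the other splits 2, and of 100 splits only the real one gave as many. Chance in the grouping is thus unlikely to give this count if the samples are independent, which the labels do not state.

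The left-right change of miR-291b-5p differed between the times by -4.95 (fitted log2, 48 h minus 12 h), by a test of the difference itself, with 3 of the 4 groups at background. The probe's signal may be real or a fault of the probe. Transcription of the whole miR-290 to miR-295 cluster is argued against, since its 7 other tested members had a median log2 change of -0.52 at 12 h (median absolute deviation 0.55), 2 above and 5 below 0. Of those above 0, miR-291b-3p, the other strand of the same hairpin, stood at 1.12 ± 1.19 SE in the fit without the detection filter. It was detected on 4 left and 2 right arrays at 12 h and on 0 at 48 h, so a rise of both strands is not excluded. Signal from the near-identical miR-291a-5p cannot be told apart. Its own probe had a log2 change of -0.0770 ± 0.0329 SE at 12 h and was detected on 0 of 24 arrays. This met the outcome set beforehand against that source. The outcome was set aside, because a probe detected nowhere is not known to respond. Processing or stability of this strand alone, in the ligated artery, stays open as untested.

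For the other counts, the splits at 12 h are too few for a share under 0.05 (real count 2, highest other 0, with 1 of 10 splits giving as many). For the difference between times chance cannot be excluded for the count (real 1, highest other 3, 67 of 100 splits giving as many). Chance is unlikely for the right carotid between times (real 107, highest other 32, 1 of 84) and the left (real 191, highest other 4, 1 of 84), if the samples are independent. Time and table coincide there.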

How the results depend on the processing

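The counts with every array as a sample, with arrays of few detected probes left out, with the detected number as a covariate, with only probes detected on all arrays, and of lists with 1 sample left out or adjusted without the 2 remembered sets were chosen after the data had been seen. Of 15 calls of named miRNAs, none turned direction under any alternative, and miR-291b-5p kept its call in all 16 unblocked alternatives at 12 h (log2 change 3.97 to 5.29) and all 28 of the difference (-5.19 to -3.84), while miR-872* kept it in 6 of 16. At 48 h solexa-284-1594 and miR-423-3p kept theirs in 24 of 25, miR-574-3p in 22, let-7d in 21, miR-26a in 20, miR-327 in 18, miR-23b in 12 and miR-99b in 10 of 25, miR-330* and miR-615-5p in 16 of 24, and miR-146b in 16 and miR-669e in 10 of 23. Counts at 12 h, 2 in the report, were 1 with no background correction, normexp with an offset of 50, the authors' values and no filter, 0 of 299 tested with only probes detected on all arrays (40 with an unadjusted p under 0.05; neither called miRNA is among these probes), 72 with every array as a sample (repeat arrays then narrow the spread), and 1 to 2 leaving out 1 sample. At 48 h the 12 became 7 without the trend, 21 with array weights, 25 with no filter, 6 without the 3 right arrays with the fewest detected probes, and 0 to 15 leaving out 1 sample. The difference between times, 1 miRNA, became 3 with cyclic loess, the strict detection filter or array weights, 2 with 75th percentile scaling, 6 with no filter, 17 with every array as a sample, 0 with the authors' values (437 tested, 33 with an unadjusted p under 0.05) and 0 with only probes detected on all arrays (220 tested, 20), both of which lack miR-291b-5p, and 1 to 9 leaving out 1 sample. Between times, only probes detected on all arrays gave 41 (right) and 91 (left) of 220 tested, and leaving out 1 sample gave 76 to 109 and 140 to 190. Of the lists at 48 h, 3 passed camera, 0 with an estimated correlation (1 with an unadjusted p under 0.05) and 1 with fry (the remembered raised set). With 1 sample left out, 2 to 4 passed. Adjusted without the 2 remembered sets, which leaves fewer lists, 1 passed. It was the laminar flow list, which holds miR-30c of the lowered set and so is not wholly independent of these samples. For the difference 0 passed, 1 with 75th percentile scaling and 0 to 2 leaving out 1 sample. At 12 h 0 passed in each of these cases (1 with an unadjusted p under 0.05 with all samples, 0 to 6 leaving out 1). With the replicate number as a block, 0 passed at 12 h (limma, 45 with an unadjusted p under 0.05), 0 at 48 h (66) and 1 for the difference, and 1 list passed for the difference. Same-numbered left and right samples correlated at 0.0245 to 0.0599 at 12 h, each best with its own number. At 48 h they correlated at -0.175 to 0.0242, none of them best. The numbers were not taken to pair samples at either time, though at 12 h these values leave pairing open. Signs of miRNAs that passed under neither setting turned as follows. At 12 h with cyclic loess, log2 changes became 0.0630 for miR-126-3p, 0.0996 for let-7d, -0.0483 for miR-195, 0.00707 for miR-30c, 0.0675 for miR-26b and -0.0875 for miR-770-5p; with array weights 0.00363 for miR-143 and 0.0480 for miR-210; with 75th percentile scaling 0.0393 for miR-126-3p, 0.00588 for miR-143, 0.175 for miR-146a, 0.0764 for let-7d, 0.00118 for miR-30c and 0.0586 for miR-26b. At 48 h they became -0.28 for miR-150 with array weights, 0.34 for miR-219 and 0.28 for miR-712* with 75th percentile scaling, -0.00617 for miR-21, -0.0726 for miR-499, -1.08 for miR-150 and 0.0748 for miR-219 without the 2 right arrays with the fewest detected probes, and -1.39 for miR-499, -1.11 for miR-150, 0.27 for miR-219 and 0.16 for miR-712* without the 3. Leaving out 1 sample gave, at 12 h, -0.18 to 0.22 for miR-143, -0.74 to 0.55 for miR-146a, -0.0642 to 0.0776 for miR-195, -0.40 to 0.0464 for miR-210, -0.0212 to 0.52 for miR-451, -1.30 to 1.97 for miR-712 and -0.42 to 0.37 for miR-770-5p, and at 48 h -0.79 to 0.20 for miR-146a, -0.66 to 0.87 for miR-150, -0.87 to 0.10 for miR-181b, -0.0306 to 0.0489 for miR-21, -0.00929 to 0.0526 for miR-486 and -0.0225 to 0.0747 for miR-92a. Except where construction is named, the cause was not tested. The slide as a block was not run, since the files name none. Signal over background limits probes such as miR-669e, miR-146b and miR-330*, undetected on most right arrays, and miR-712, undetected on some.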

Other observations

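The miRNAs in this part were chosen after their values were seen, and their differences are hypotheses at most.

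Detection on all left arrays and on no right array picked out 4 miRNAs at 12 h and 1 at 48 h, with 0 the other way at either time. Besides miR-291b-5p and miR-872*, these were miR-9, abundant in neural tissue and induced by NF-kB in immune cells, at least 4.33-fold higher on the left at 12 h (fitted log2 change 4.20 ± 1.01 SE, adjusted p = 0.251), and miR-1194, at least 3.15-fold higher (3.17 ± 1.05 SE, adjusted p = 0.373). At 48 h it was miR-697, at least 1.84-fold higher (1.67 ± 0.57 SE, adjusted p = 0.137). None of these last 3 passed the threshold. Of the 10 splits of the samples at 12 h, 3 gave as many such miRNAs (highest other 5), and 18 of 462 did at 48 h (highest other 2).

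miR-1, the muscle miRNA, had low values on the left at both times, with a log2 change of -4.03 ± 1.16 SE at 12 h (adjusted p = 0.297; detected on 2 left and 6 right arrays) and -4.12 ± 1.53 SE at 48 h (adjusted p = 0.158; 1 left and 4 right arrays). Neither passed. miR-133a and miR-133b, transcribed with miR-1 family genes in muscle, stood at -0.17 ± 0.58 SE and 0.14 ± 0.35 SE at 48 h. At 12 h miR-133a stood at 1.11 ± 0.34 SE (adjusted p = 0.363), opposite in sign to miR-1, and miR-133b was below the detection filter.

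The passenger strand let-7i* stood at 3.39 ± 0.99 SE at 48 h (adjusted p = 0.102; detected on 6 left and 2 right arrays), while let-7i itself stood at -0.77 ± 0.49 SE (adjusted p = 0.424). With most right arrays at background, the size for let-7i* depends on the background level, and the difference between the strands was not tested.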
